A study of Drosophila melanogaster with 4 samples.

How the data were processed

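The series holds 4 RNA-seq libraries from guts of Oregon R-C females, 2 from flies on a chemical diet with no manganese added and 2 from flies on the diet with 5 ppm manganese. Per the labels' protocols, total RNA was purified with a column kit and sequenced on an Illumina NextSeq instrument. The authors deposited 1 table of RPKM values, with 13932 FlyBase gene identifiers and 1 column per library. The submitters' processing notes name STAR 2.5.2b, DESeq2 and the genome build dm6, without saying which step each served. The annotation, the program that counted reads, its strand setting and its treatment of reads that match several genes are not given in the sources used here. RPKM divides by library total and by gene length, so a value depends on how many other reads a library holds, and RNA from another tissue in a library lowers all its other values slightly.

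The table's columns name the diet and a letter, B or C, while the labels number the samples, so a column was assigned to its diet and not to a numbered sample; all columns were used. Gene symbols, positions and exon lengths came from the Ensembl 115 annotation of the BDGP6 assembly, whose coordinates are those of dm6; 13852 identifiers had a symbol and 80 had none. Depth was recovered from the values: in genes of low level, RPKM times exon length is a whole multiple of a step that gives the library's divisor. With the divisors found, 84.6% to 85.5% of values under 20 reads came within 0.02 of a whole number of reads. The divisors were 26122210 and 26311006 reads without manganese and 24399759 and 28010953 with it, so 3 reads in 1000 bases are worth 0.107 to 0.123 RPKM. In the tested genes, 0 values were identical between the no-manganese libraries and 2 between the 5 ppm libraries, so no column is a copy of another. Each library was counted as its own replicate, although differing values do not exclude repeated preparations of the same RNA.

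The test used limma 3.58.1 in R 4.3.3 on log2(RPKM + 1), with genes of a mean of at least 1 RPKM over the 4 libraries (7556 genes), a trend in the prior variance (2.58 prior degrees of freedom) and 2 residual degrees of freedom. Fold changes are no manganese minus 5 ppm on that scale, which understates the change of low genes. The P values were 2-sided and adjusted by Benjamini-Hochberg, with a threshold of 0.05. An exact permutation test of 2 against 2 libraries cannot go below p = 0.333, so none was used for single genes. Lists of genes were tested with camera at a preset correlation of 0.01 when at least 5 members were tested, adjusted over the 34 such lists out of 38 written, and again with an estimated correlation, which leaves 2 degrees of freedom; fry was run beside it. With the estimated correlation 0 of the 6 lists called held. The fry test asks whether a list's genes move one way on balance. It gave adjusted p = 0.20 for nuclear oxidative phosphorylation and for carbohydrate digestion. For the other lists called, fry gave adjusted p = 0.29 to 0.88, so none of the lists passed it. Of the list members written, 14 matched no symbol.

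The lists, the tests, the alternatives and the rule for the genes named were fixed before the data were examined. The rule takes the 10 genes with the largest change in each direction among those past the threshold with no overlap between diets, filled up with the smallest unadjusted p among genes with an absolute log2 fold change of at least 1 and no overlap, which are said not to pass. It adds 12 genes of manganese, iron and metal handling in every case, and up to 4 members with the smallest unadjusted p from each list described. Lip3, Oat, dec, Vm34Ca, Vm26Aa, FASN1, SREBP, Amy-p, Amy-d, Muc11A, osk, yl, Cp15, Cp36, mRpS16 and mRpL55 were named after their values were seen. Overlap of exons with other genes was taken from the annotation.

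The fits were tested on simulated data for this comparison, 20 runs over 7506 genes with 200 changed genes in each, drawn independently of each other. They called 46.7% of genes changed 2-fold, 90.5% of those changed 4-fold, 97.6% of those changed 8-fold and 0.125% of unchanged genes. The changed genes, some by 16-fold, loosen the adjusted threshold for all genes. Differences between the real libraries, such as the eggshell RNA and the length trend, were not simulated. In the real data, prt and CG14075, with log2 fold changes of -2.62 and 2.55, had a limma adjusted p of 0.261. These shares therefore do not show that 4-fold changes are absent. A list of 69 genes raised by 0.25 was called in 20 of 20 runs, and random lists of unchanged genes reached an unadjusted p under 0.05 in 0.75% of 400 tests; genes that vary together, as in real lists, were not simulated.

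Alternatives were a pseudocount of 0.1 or 5, no filter or a mean of at least 5 RPKM, median, quantile and trimmed mean scaling, robust empirical Bayes, no trend, the library letters as a block, and each library left out in turn, where a lone library is assumed to vary like those of the other diet. Added after seeing the data were voom on the recovered reads, with and without the letters as a block, removal of each library's trend with exon length by loess, and the carbohydrate digestion list without its alpha-mannosidases. Count models were not run, because the values are RPKM and whole reads were recovered for part of the genes. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.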

Results

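Gut RNA was sequenced from female fruit flies (Drosophila melanogaster) of Oregon R-C, a standard wild-type laboratory strain, to ask which genes respond when manganese is left out of the food. The food was a chemical diet to which either no manganese or 5 ppm manganese had been added. On each diet, the parents were 10 females and 10 males, with 5 days of egg laying. Young adult daughters were then kept for 5 days on fresh food of the same kind before their guts were taken. Each diet has 2 libraries, called B and C here after the letters in the table. The table gives RPKM, reads scaled to transcript length and library total, for 13932 genes. Most of its low values are steps of whole reads, which puts the depth at 26122210 and 26311006 reads for the no-manganese libraries B and C. The 5 ppm libraries B and C had 24399759 and 28010953 reads. Between 10610 and 10739 genes were above 0 in a library. Nothing in the labels says that the libraries of a diet came from separate groups of flies, so the tests measure the spread between these libraries, which may be technical.

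Without manganese, genes that encode the oxidative phosphorylation machinery of mitochondria were higher as a group, and genes for glycosidases such as the maltases and for glucose processing were lower as groups. These calls rest on a preset correlation between genes: with an estimated one, 0 of 34 lists passed (adjusted p = 0.81 for each of these 3). Among single genes, CG14075 had 6.31 ± 0.0722 RPKM (mean ± SD, n = 2) without manganese and 0.269 ± 0.294 with it. The vesicular transporter-like gene prt had 1.85 ± 0.716 RPKM without manganese and 16.3 ± 1.91 with it. No single gene passed the test, so these values and those of the genes named next are differences without a call. Of 7556 genes tested with limma, 0 were higher and 0 lower at an adjusted p under 0.05, and the smallest adjusted p was 0.261. At an unadjusted p under 0.05 there were 218 higher and 223 lower genes, 441 in all, where 378 are expected by chance. That count depends on the fit. With the library letters as a block, 446 genes were higher and 432 lower at that level (limma, smallest adjusted p 0.0659). Whether the letters pair the libraries is not known. With voom on reads recovered from the RPKM, 0 genes were higher and 0 lower as well, with 204 higher and 239 lower at an unadjusted p under 0.05. Those reads are approximate, because 78.0% to 78.3% of all values came close to a whole number of reads and the rest were rounded. Without the no-manganese library B, 10 genes were higher and 1 lower, and without the no-manganese library C, 5 were higher and 0 lower.

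The genes listed here had at least a 2-fold difference on the log2 scale of RPKM + 1 and no overlap between the diets, the smallest unadjusted p-values among such genes, and adjusted p-values that did not pass. On the higher side, Akh, the adipokinetic hormone made in the corpora cardiaca next to the foregut, had 5.05 ± 0.0257 RPKM without manganese and 0.476 ± 0.457 with it (log2 fold change 2.07 ± 0.25 SE). Npc2c, of a family of sterol-binding proteins, had 6.01 ± 1.67 against 0.849 ± 0.273 RPKM (1.91 ± 0.22 SE). An antisense gene covers 58.5% of its exon bases, and their reads cannot be told apart because the strand setting of the counting is not given in the sources used here. MsrA, a methionine sulfoxide reductase that repairs oxidised proteins, had 232 ± 115 RPKM without manganese and 48.0 ± 21.8 with it (2.23 ± 0.48 SE). The other 6 genes of this side were CG32483, CG5550, lcs, CG11912, CG6296 and CG42728, with log2 fold changes between 1.03 and 1.43. On the lower side, the glucocerebrosidase genes Gba1a and Gba1b had log2 fold changes of -1.12 ± 0.19 SE and -1.03 ± 0.12 SE. Gba1a had 393 ± 22.8 RPKM without manganese and 864 ± 181 with it. Gba1a and Gba1b are paralogs, so reads shared between the copies leave the value of the weaker Gba1b uncertain, and 24.0% of its exon bases lie under an antisense gene. CG31468 was at 1.01 ± 0.145 RPKM without manganese and 5.49 ± 0.395 with it (-1.69 ± 0.13 SE). The genes prt, CG31468, Gba1a and Gba1b lie close together on chromosome 3R, between 23696372 and 23708512. Their lower values may therefore be a single local difference and not separate ones. The peroxiredoxin Prx6b, the glutathione transferase GstD8, the cytochrome P450 Cyp4d8, CG1271, CG10383 and Rab3-GEF, a regulator of vesicle release, had log2 fold changes between -1.01 and -1.47. In all, 32 genes were higher and 30 lower by at least that much with no overlap. Among all tested genes 1638 higher and 1148 lower had no overlap, 36.9% of them, where chance gives 33.3%. CG14075 (FBgn0036835) lies on chromosome 3L from 18984961 to 18985634 on the plus strand of the dm6 assembly, as a protein-coding gene with 674 exon bases.

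**Figure D1:**
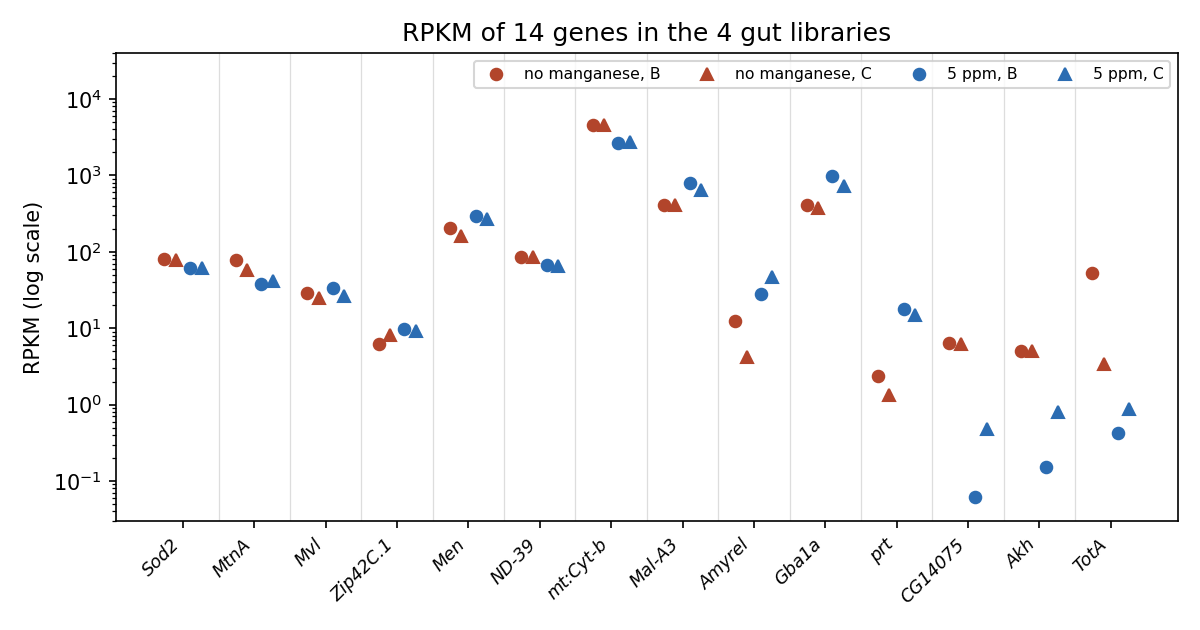
RPKM (log axis) of 14 genes, each point 1 library: circles library B, triangles library C, red without manganese and blue with 5 ppm. CG14075 lies near 6.31 RPKM in the libraries without manganese and below 0.5 RPKM in the others; TotA stands at 53.4 RPKM in the no-manganese library B and at 3.41 in library C of that diet.

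The nuclear genes of oxidative phosphorylation, which encode subunits of the respiratory chain and the ATP synthase, rose without manganese as a list. Of 69 tested members 66 were higher and 3 lower, and 63 of the higher ones had no overlap between the diets. The median log2 fold change was 0.28, a 1.22-fold rise (camera, adjusted p = 7.1e-21; adjusted p = 0.81 with an estimated correlation). None of the 69 passed singly, either over all genes tested or adjusted over the list alone. ND-39, a subunit of complex I, had 85.7 ± 0.152 RPKM without manganese and 66.7 ± 1.04 with it. The complex I subunits ND-23 and ND-AGGG had log2 fold changes of 0.40 ± 0.11 SE and 0.74 ± 0.16 SE. ATPsyndelta, a subunit of the ATP synthase, was at 0.34 ± 0.10 SE, and 35.6% of its exon bases are shared with CG2962 on the opposite strand. The 2 no-manganese libraries lay alike on this list, with medians of 0.25 in B and 0.28 in C above the mean of the 5 ppm libraries. Fold changes ran with exon length over the 7506 genes with a gene model (Spearman's rho -0.27 across genes, which are not independent replicates), short genes being higher, and this list has a median exon length of 871 bases. Genes encoded in the mitochondrial genome rose as well, 12 of 13 members being higher. Their median log2 fold change was 0.37 (adjusted p = 0.00019, and 0.91 with an estimated correlation). Of the members, 0 passed over all genes tested or adjusted over the list alone. The estimated correlation between them was 0.462, so the count of higher members is not separate evidence. Grouped by letter instead of diet, the libraries also differed on this list (absolute median 0.20, camera, adjusted p = 0.022). mt:Cyt-b, of complex III, had 4516 ± 4.68 RPKM without manganese and 2709 ± 95.3 with it, and mt:CoI, of complex IV, had 9414 ± 479 and 6281 ± 119. Log2 fold changes were 0.60 ± 0.20 SE for mt:CoIII and 0.50 ± 0.20 SE for mt:ND4. Together the mitochondrial genome took 6.14% and 6.82% of all RPKM in the no-manganese libraries and 4.42% and 4.65% in the 5 ppm libraries. Without the no-manganese library C this list no longer passed (median 0.27, adjusted p = 0.086), and without the 5 ppm library B its median was 0.18 (adjusted p = 0.042).

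**Figure D2:**
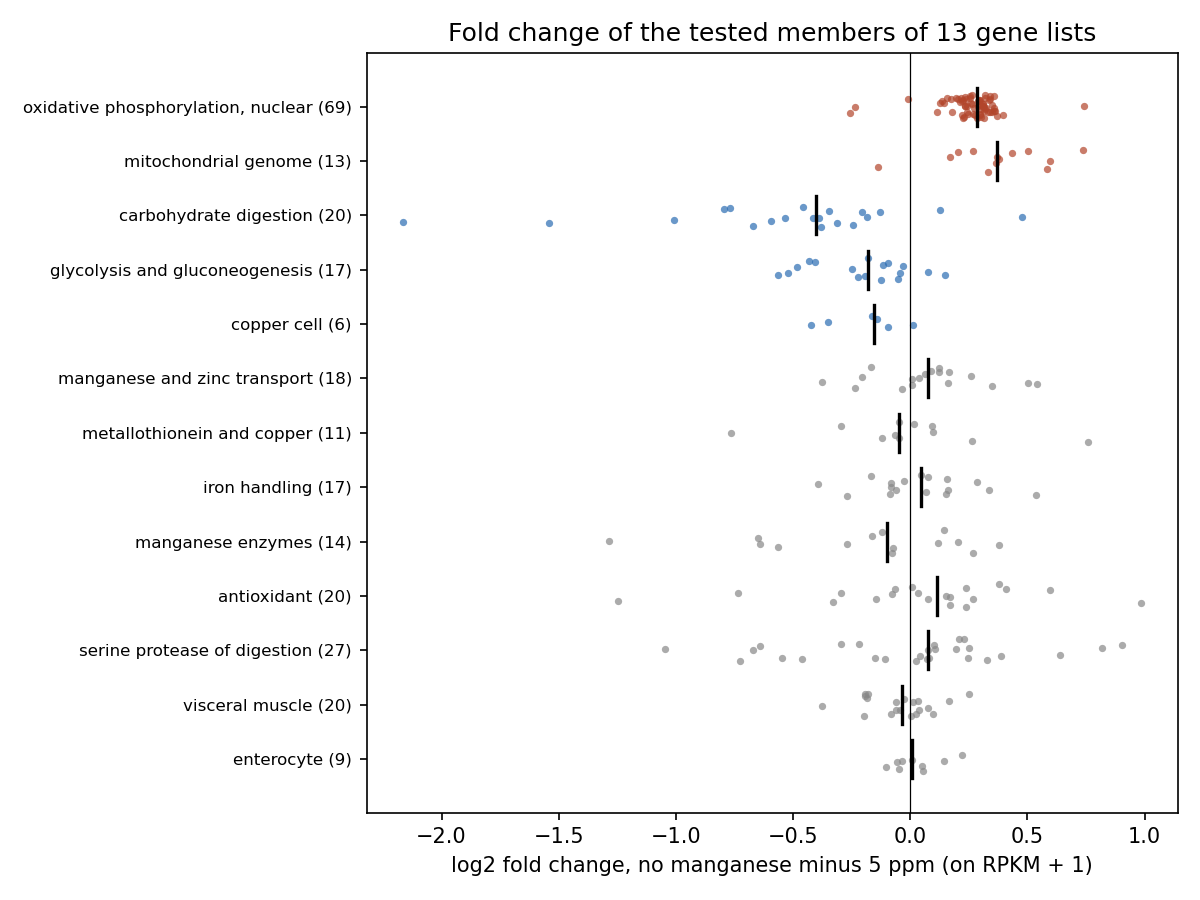
Log2 fold change (x axis, no manganese minus 5 ppm, on RPKM + 1) of each tested member of 13 gene lists, with the number tested in brackets and the list median as a black bar. Red lists rose and blue lists fell by camera with the preset correlation, grey lists did not pass. The 69 nuclear oxidative phosphorylation genes gather around 0.28, while manganese and zinc transport genes lie on both sides of 0 (heights within a row are random).

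Genes of the carbohydrate digestion list fell without manganese as a list, which holds 9 maltases, 3 amylase genes, tobi, Treh and 6 lysosomal alpha-mannosidases. Of 20 tested members 18 were lower and 2 higher, 11 of the lower ones with no overlap. The median log2 fold change was -0.40 (adjusted p = 1.1e-07; adjusted p = 0.81 with an estimated correlation). Without the alpha-mannosidases, left out after the values were seen, 13 of 14 were lower (median -0.37, adjusted p = 1.8e-06; adjusted p = 0.87 with an estimated correlation). Singly, 0 members passed over all genes tested or adjusted over the list alone. The maltases Mal-A1 to Mal-A8 lie together on chromosome 2R, between 8449664 and 8473961, and LManIII to LManVI together on 2L. The counts of lower members are therefore not separate evidence. LManIII to LManVI were each highest in the 5 ppm library B, and for most of them library C of that diet lay near the no-manganese values. The maltase Mal-A3 had 411 ± 6.09 RPKM without manganese and 717 ± 109 with it, and Amyrel, an amylase-related gene, 8.24 ± 5.75 and 37.4 ± 13.7. The amylases Amy-p and Amy-d lay on both sides of 0, without a call, and as near-identical copies their separate values are uncertain. Amy-p had 2747 ± 1110 RPKM without manganese and 1913 ± 424 with it, and Amy-d 1127 ± 493 and 1420 ± 302. Their sum was 3437 and 4310 RPKM without manganese and 3847 and 2820 with it. Log2 fold changes were -0.46 ± 0.12 SE for Mal-A5 and -0.67 ± 0.21 SE (-0.94 to -0.41 with 1 library left out) for Treh, which splits trehalose. Glycolysis and gluconeogenesis genes fell as well, 15 of 17 being lower. Their median was -0.18 (adjusted p = 0.00025; adjusted p = 0.81 with an estimated correlation), and 0 members passed over all genes tested or adjusted over the list alone. Without the 5 ppm library B the median was -0.08 (adjusted p = 0.033). Of its 4 members with the smallest p-values, Zw and Pgd belong to the pentose phosphate pathway, which supplies NADPH. They had 23.2 ± 2.48 and 44.5 ± 1.27 RPKM without manganese against 32.9 ± 4.08 and 60.5 ± 5.88 with it. Pgi, shared by glycolysis and gluconeogenesis, and fbp, of gluconeogenesis, had log2 fold changes of -0.41 ± 0.12 SE and -0.52 ± 0.18 SE. Lipid metabolism genes did not pass as a list, with 18 of 27 lower and a median of -0.06 (adjusted p = 0.066; adjusted p = 0.91 with an estimated correlation). They were called lower without the no-manganese library C (-0.19, adjusted p = 0.0061) and without the 5 ppm library C (-0.13, adjusted p = 0.041). Within it, Npc2c was the 1 member to pass adjusted over the list alone (adjusted p = 0.015), and it was higher. ACC, which makes malonyl-CoA, and ATPCL, which makes cytosolic acetyl-CoA, had log2 fold changes of -0.72 ± 0.14 SE and -0.79 ± 0.17 SE, and Npc1b, needed for sterol uptake, -0.56 ± 0.15 SE.

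The genes most directly tied to the missing metal showed no called difference as 1 set. The question was put to 92 tested genes of metal transport, metallothioneins, iron handling, manganese enzymes, glycosyl transferases and antioxidant defence. Of these, 0 passed over all genes tested and 0 adjusted over the 92 together (smallest adjusted p = 0.0712), with 6 at an unadjusted p under 0.05. Without the 5 ppm library C, 1 passed adjusted over those tested together, Oat, with a log2 fold change of -2.04. Its value was -1.29 ± 0.51 SE with all libraries and -0.53 without the 5 ppm library B. Mvl, the fly NRAMP transporter that takes up manganese and iron, had 26.6 ± 2.90 RPKM without manganese and 30.1 ± 4.86 with it. The zinc and manganese transporter family members Zip42C.1, Zip71B and Zip99C had log2 fold changes of -0.38 ± 0.15 SE, 0.12 ± 0.20 SE and -0.20 ± 0.15 SE. SPoCk, a calcium and manganese pump of the Golgi, was at 0.06 ± 0.10 SE. Manganese and zinc transport genes did not pass as a list (13 of 18 higher, median 0.08, adjusted p = 0.88), and Zip88E, Zip48C and Zip42C.2 had log2 fold changes of -0.24, 0.35 and 0.54. With 1 library left out, Zip48C ran from 0.19 to 0.51 and Zip42C.2 from 0.27 to 0.81. Among manganese enzymes, Sod2, the mitochondrial superoxide dismutase that carries manganese, had 79.2 ± 1.25 RPKM without manganese and 60.7 ± 0.306 with it (0.38 ± 0.09 SE). The malic enzymes Men and Men-b, which make NADPH, lay on the other side, with 183 ± 33.3 and 210 ± 39.8 RPKM without manganese against 283 ± 20.8 and 327 ± 11.2 with it. As a list the manganese enzymes did not pass (5 of 14 higher, median -0.10, adjusted p = 0.27). Gs1, a glutamine synthetase, had a log2 fold change of -0.12 ± 0.20 SE. The arginase gene arg lay below the level tested, with 0.308, 0.764, 0.231 and 0.977 RPKM in the no-manganese libraries B and C and the 5 ppm libraries B and C. MtnA, a metallothionein that binds copper, had 68.4 ± 14.1 RPKM without manganese and 39.7 ± 3.27 with it (0.76 ± 0.17 SE). MtnB was at 0.10 ± 0.22 SE, MtnD at -0.29 ± 0.12 SE and the copper importer Ctr1B at -0.76 ± 0.30 SE (-1.19 to -0.34 with 1 library left out). The metallothionein and copper list (5 of 11 higher, median -0.05, adjusted p = 0.67) and the iron list (9 of 17 higher, median 0.05, adjusted p = 0.90) did not pass. The ferritin subunits Fer1HCH and Fer2LCH had log2 fold changes of 0.05 ± 0.17 SE and -0.03 ± 0.20 SE, Irp-1B, an iron regulatory protein, -0.27, and the multicopper oxidase Mco1 0.29. Glycosyl transferases, many of which use manganese, did not pass (12 of 15 higher, median 0.10, adjusted p = 0.16), with tgy at 0.21 and Pgant4 at 0.31. The median log2 fold change of all tested genes was 0.024.

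Antioxidant genes went both ways. Of 20 tested, 13 were higher and 7 lower, with a median of 0.11 (adjusted p = 0.90). Prx6b, which did not pass over the 92 genes above, was the 1 member past the test adjusted over these 20 alone (adjusted p = 0.015), at 1.89 ± 0.00962 RPKM without manganese and 5.91 ± 1.17 with it. Catalase, Cat, had a log2 fold change of -0.33 ± 0.12 SE and the peroxiredoxin Prx4 0.24 ± 0.09 SE. Glutathione transferases also went both ways, 17 of 31 being higher (median 0.07, camera direction down, adjusted p = 0.91). GstD8 was the 1 member past the test adjusted over the list alone (adjusted p = 0.047), at 26.8 ± 1.24 RPKM without manganese and 62.8 ± 13.8 with it. GstT4, GstT3 and GstO3 had log2 fold changes of -0.46, -0.65 and 1.16. Cytochrome P450 genes did not pass (27 of 57 higher, median -0.02, adjusted p = 0.23), with Cyp311a1 at -0.53, Cyp4ac3 at -0.49 and Cyp309a1 at -0.60. Digestive serine proteases did not pass (17 of 27 higher, median 0.07, adjusted p = 0.49). Jon74E, a jonah-type protease, passed adjusted over the list alone (adjusted p = 0.013) with 22.0 ± 0.530 RPKM without manganese and 11.3 ± 0.865 with it. Jon65Aiii was at 0.82 ± 0.16 SE and deltaTry, a trypsin with near-identical copies and so an uncertain value, at 0.64 ± 0.21 SE. Npc2c, Prx6b, GstD8 and Jon74E, 2 higher and 2 lower, were the members past the test adjusted over their list alone, among 674 members of 34 lists. That adjustment does not correct across lists, so a few such passes can arise by chance. Antimicrobial peptide genes did not pass (7 of 12 higher, median 0.38, adjusted p = 0.23), with Drsl3 at 0.42, CecC at 0.96 and AttD at -0.99. With 1 library left out, CecC ran from 0.41 to 1.52 and AttD from -1.45 to -0.53. The lists of peptidoglycan recognition and lysozyme (adjusted p = 0.21), peritrophic matrix (0.23), cell cycle (0.23), vacuolar ATPase (0.73), circadian clock (0.80) and heat shock (0.90) did not pass. Nor did those of amino acid transport and insulin response (0.90), cytosolic ribosomal proteins (0.96), endoplasmic reticulum stress (0.97) and UDP-glycosyltransferases (0.97). Some of these lists were called when a library was left out, at the preset correlation; in the full set an estimated one gave them adjusted p = 0.91 to 0.99. Cytosolic ribosomal proteins were lower without the 5 ppm library B (median -0.11, adjusted p = 2.4e-06) and higher without the 5 ppm library C (0.15, adjusted p = 3.9e-08). Antimicrobial peptides were higher without the no-manganese library C (adjusted p = 0.0043) and without the 5 ppm library C (adjusted p = 0.00025), and serine proteases without the 5 ppm library B (adjusted p = 5.9e-06). Peptidoglycan recognition and lysozyme genes were lower without the no-manganese library B (-0.43, adjusted p = 0.0011) and without the 5 ppm library C (-0.15, adjusted p = 0.0098). Peritrophic matrix genes were called higher without the no-manganese library C (median 0.31) and cell cycle genes without B of that diet (median 0.08). The cell cycle call then rests on library C, which held the eggshell and germline RNA described below. Cytochrome P450 genes were lower without the 5 ppm library B (adjusted p = 0.033).

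Of the lists of gut cell markers, copper cells passed and the others did not, while eggshell genes set a single library apart. Absorptive enterocyte genes such as mex1 and Myo61F had a median log2 fold change of 0.01 (9 tested, adjusted p = 0.97). Visceral muscle genes had -0.04 (20 tested, adjusted p = 0.34), with Mf at 0.25 and Prm at -0.18, and progenitor genes -0.06 (7 tested, adjusted p = 0.34). Enteroendocrine genes had 0.01 (12 tested, 7 higher and 5 lower, adjusted p = 0.52). Among the lower ones, the peptide hormones CCHa1 and AstA were at -0.34 and -0.53 (AstA -0.73 to -0.33 with 1 library left out). Malpighian tubule genes (7 tested, median 0.00, adjusted p = 0.86) did not pass. Genes of copper cells, the acid-secreting cells of the midgut, fell as a list of 6 with 5 lower and a median of -0.15 (adjusted p = 0.040; adjusted p = 0.91 with an estimated correlation). It was led by alpha-Spec, a membrane skeleton protein of many tissues, at -0.42 ± 0.10 SE and Vha100-4, a proton pump subunit, at -0.35 ± 0.17 SE (-0.57 to -0.13 with 1 library left out); 0 members passed over all genes tested or adjusted over the list alone. That call ended without the no-manganese library B (median -0.03, adjusted p = 0.34) and without the 5 ppm library B (median -0.13, adjusted p = 0.16). The median was -0.31 without the no-manganese library C and -0.24 without the 5 ppm library C. Eggshell genes passed the list test as higher without manganese (8 of 8 members, median 2.71, adjusted p = 0.022; adjusted p = 0.91 with an estimated correlation), yet their RNA lay in the no-manganese library C. Their summed level was 570 RPKM there, 1.49 RPKM in the no-manganese library B, and 2.77 and 5.21 RPKM in the 5 ppm libraries. The vitelline membrane genes Vm34Ca, Vm26Aa and Vm26Ab stood at 209.9, 142.6 and 67.5 RPKM in that library and at most at 0.44, 0.34 and 0.06 RPKM in the others, whereas Vml, Vm32E and Vm26Ac were at 23.4, 35.3 and 10.6 RPKM. Without that library fewer than 5 eggshell genes were left to test, and without the 5 ppm library B the list did not pass (median 2.59, adjusted p = 0.13). The yolk genes Yp1 and Yp2, expressed in fat body and follicle cells, were at 179 and 391 RPKM in the same library and at 81.3 and 131 in the no-manganese library B. They were at 55.6 and 76.1 RPKM in the 5 ppm library B and at 110 and 177 in library C. The fat body list did not pass (6 tested, median 0.56, adjusted p = 0.52), but was called higher without the 5 ppm library C (median 1.20, adjusted p = 0.00019; adjusted p = 0.99 with an estimated correlation in the full set). Lists with fewer than 5 tested members, female germline, hemocyte, neuron and male reproductive tract, had median levels of 2.22 RPKM or less in every library. Without the no-manganese library B, 7 germline genes could be tested and were called higher (median 1.41, adjusted p = 2e-06). Of the genes passing when the no-manganese library B was left out, prt was lower (log2 fold change -2.88) and 8 of the 10 higher ones, among them Vm34Ca, Vm26Aa and dec, belong to the eggshell list.

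The no-manganese library B stood apart in another group. The stress-induced Turandot genes TotA, TotM and TotC, targets of JAK-STAT signalling, had 53.4, 40.2 and 24.2 RPKM in that library, 3.41, 2.00 and 1.15 in the no-manganese library C, and at most 0.863, 0.520 and 0.606 in the 5 ppm libraries. The Turandot and JAK-STAT list did not pass (7 of 9 higher, median 0.57, adjusted p = 0.070). It passed with a pseudocount of 0.1 (median 0.93, adjusted p = 0.043), with no filter on low values (0.34, adjusted p = 0.038), with the length trend removed (0.53, adjusted p = 0.011) and without library C (1.02, adjusted p = 8e-09). These calls use the preset correlation, and with an estimated one the full set gave adjusted p = 0.91. Heat shock genes had medians of 0.88 in library B and -0.31 in C against the mean of the 5 ppm libraries. With all libraries this list did not pass by camera (median 0.23, adjusted p = 0.90, and 0.99 with an estimated correlation). Without the no-manganese library C it was called higher (median 0.88), with library B alone left for that diet. Grouped by letter instead of diet, the B and C libraries differed on the heat shock list by an absolute median of 1.01 (camera, adjusted p = 0.00046). Heat shock genes thus ran with the letters and did not set the no-manganese library B alone apart. TotA and TotM were among the 5 genes that passed when library C was left out, with log2 fold changes of 5.06 and 4.83. Over all tested genes, log2 RPKM + 1 correlated at r = 0.978 between the no-manganese libraries and at 0.988 between the 5 ppm libraries, against 0.976 to 0.986 between libraries of different diets, across genes and without a test. The first principal component, with 49.8% of the variance, set the no-manganese library C apart at 23.6 from -13.7 to 1.1 in the others. The next, with 32.1%, separated the diets, at -17.0 and -4.5 without manganese and 7.2 and 14.3 with it.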

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

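Voom on recovered reads, its fit with the library letters as a block, removal of the length trend and leaving out the alpha-mannosidases were chosen after seeing the data; the other settings were planned. Count models were planned but not run, because the values are RPKM. The count of 0 genes in each direction held under all settings that kept the 4 libraries (smallest adjusted p 0.0659 to 0.715). Leaving out 1 library gave 0 to 10 higher genes, 0 to 1 lower genes, 7 to 11 called lists where the full set gave 6, and 0 to 1 metal and redox genes. A diet was then left with 1 library. With an estimated correlation 0 lists were called, with the medians as before (oxidative phosphorylation 0.28, mitochondrial genome 0.37, carbohydrate digestion -0.40, glycolysis -0.18, eggshell 2.71, copper cell -0.15). That test allows for genes of a list varying together, but it leaves 2 degrees of freedom. A list can hardly pass it, so the loss alone does not show that such variation made the calls. The estimated correlations of the called lists nevertheless lay above the preset 0.01. They were 0.172 for nuclear oxidative phosphorylation, 0.462 for the mitochondrial genome and 0.22 for copper cells. Carbohydrate digestion had 0.03, glycolysis 0.039 and eggshell 1. Shared variation as a source of the calls therefore stays open. The nuclear oxidative phosphorylation, carbohydrate digestion and glycolysis lists kept direction and call under the other settings run, with adjusted p from 1.3e-22 to 5.6e-12, from 1.7e-10 to 0.00064 and from 9.8e-05 to 0.033. Leaving out libraries gave 0.18 to 0.50 for the mitochondrial genome, -0.31 to -0.03 for copper cells and 2.59 to 5.18 for eggshell. Copper cell genes lost the call with no filter (-0.14, adjusted p 0.062), at a mean of at least 5 RPKM (-0.16, 0.071), with voom (-0.17, 0.057), with voom and the block (-0.17, 0.054) and without the length trend (-0.16, 0.074). Eggshell genes lost it with no filter (0.14, 0.27, over 18 genes instead of 8), at a mean of at least 5 RPKM (2.94, 0.071) and with voom (4.06, 0.30). The cause was not tested, apart from the number of genes tested in the filters. What the letters mark is not given in the sources used here. Deviations from the diet means correlated at 0.34 between libraries of the same letter, which with 2 pairs does not settle whether they pair the libraries. The fit with the replicate block called 0 genes higher, 0 lower (446 and 432 at an unadjusted p under 0.05, where 378 in all are expected by chance) and 9 lists: the 6 of the main fit, Turandot (adjusted p 0.020) and fat body genes (0.0096) as higher, and peptidoglycan recognition and lysozyme genes (0.030) as lower. With voom and the block these 3 were called as well. Beyond the Turandot list, other fits of the 4 libraries called lipid metabolism genes lower at a mean of at least 5 RPKM (adjusted p 0.0056), cell cycle genes higher with no filter (0.026) and glycosyl transferases higher without the length trend (0.044). Of 1776 pairs of a named gene and a setting, 12 turned direction: Amy-d (-0.85 to 0.07), Fer1HCH (-0.10 to 0.19), Fer2LCH (-0.22 to 0.16), Gs1 (-0.34 to 0.10), MtnB (-0.13 to 0.33), SPoCk (-0.01 to 0.13) and Zip71B (-0.13 to 0.37) with libraries left out, and MtnB at -0.02 without the length trend. With 1 library left out, 46 of 106 named genes moved by over 1.5 times. The scalings shifted the median of all genes by -0.023 to -0.014. The similarity of libraries within against between diets, 0.0008 in mean r, was -0.0003 with a pseudocount of 0.1 and 0.0016 at a mean of at least 5 RPKM. It is near 0 and without a settled sign. Depth limits low genes: over 1000 exon bases, 3 reads amount to 0.107 to 0.123 RPKM.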

Other observations

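Chosen only after the result was seen were the tests of egg chambers and muscle for the oxidative phosphorylation genes, of other splits, of the eggshell share and of library B for the length trend. The 6 gene lists named next were drawn up after the oxidative phosphorylation result. Genes of the mitochondrial ribosome, which translates the proteins encoded in the mitochondrial genome, were higher without manganese in 70 of 71 tested members. The median log2 fold change was 0.22 (camera, adjusted p = 4.3e-15 over 5 added lists, without the list of the next paragraph; adjusted p = 0.57 with an estimated correlation). The median was 0.14 in the no-manganese library B and 0.29 in C, and 0.12 with the length trend removed, and a shared rise of mitochondrial genes is the hypothesis behind this test, which was written before the values of this list were seen. mRpS16 and mRpL55 were at 0.53 ± 0.10 SE each, without passing. Cytosolic aminoacyl-tRNA synthetases were higher in 16 of 17 (median 0.12, adjusted p = 0.011; 0.57 as adjusted p with an estimated correlation), mostly in library C (median 0.23, against 0.05 in B). Tricarboxylic acid cycle genes (median 0.15, adjusted p = 0.065), mitochondrial protein import genes (0.13, adjusted p = 0.26) and proteasome genes (0.01, adjusted p = 0.31) did not pass.

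Genes that supply NADPH or make fatty acids were lower without manganese in 9 of 9 tested members, with a median log2 fold change of -0.48. The list was drawn up after ACC, ATPCL, Men, Men-b, Zw and Pgd had been seen to be lower, so a test of it is void and none is given. SREBP, the regulator of lipid synthesis genes, had 55.6 ± 0.331 RPKM without manganese and 70.1 ± 6.39 with it, and FASN1, the fatty acid synthase, a log2 fold change of -0.42 ± 0.22 SE (-0.73 to -0.11 with 1 library left out). Lip3, a lipase, stood at 9.32 and 12.3 RPKM without manganese and at 105 and 28.2 with it.

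For the rise of nuclear oxidative phosphorylation genes, a trend of fold change with transcript length was tested as the whole cause. It is argued against by a median of 0.19 (0.28 before) after each library's length trend was removed (camera, adjusted p = 2.3e-15). Random lists matched on length and level had a median of medians of 0.04, and 0 of 10000 reached 0.28 (highest 0.16). Their genes were drawn singly, unlike list members that vary together. That count therefore does not measure chance. Egg chamber RNA in the no-manganese library C is argued against by a median of 0.25 without that library, where the list was still called at the preset correlation. More visceral muscle is argued against by a muscle median of -0.04 ± 0.04 (bootstrap SE). That SE comes from resampling the muscle genes and not the libraries, so it does not measure variation between gut preparations. The 4 libraries make 3 splits into pairs, too few for a share under 0.05; the real split gave a median of 0.28, the highest of the others was 0.04, and 1 split, the real one, reached as small a p. The split by letter, B against C, called 9 lists and the remaining split 7, where the real one called 6. Among those called by letter were the mitochondrial genome (median 0.20, adjusted p = 0.022), fat body (1.19, 0.00019) and heat shock genes (1.01, 0.00046). Differences between libraries that do not follow diet thus call as many lists. A response of mitochondrial genes to the diet stays open as a hypothesis, beside chance.

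The eggshell RNA in the no-manganese library C is argued against as an effect of diet alone by the no-manganese library B, which held 0.26% of its eggshell RPKM. Egg chambers left on the guts at dissection are a candidate source and stay open. Of 13 germline genes 12 had their highest value in that library, with osk at 18.2 RPKM and yl at 7.10 against at most 0.62 and 0.26 elsewhere. The median difference of that list from the other libraries was 0.72, however, under the bound of 1 set before. Of 18 eggshell genes 8, of the vitelline membrane and other early eggshell, were above 10 RPKM there, while chorion genes made late, such as Cp15 and Cp36, had 0.15 and 1.94 RPKM.

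Long transcripts were lower without manganese, from a median of 0.10 in the shortest decile of genes to -0.12 in the longest. The trend was steeper in the no-manganese library B (rho -0.35) than in C (rho -0.11, which is the value without library B), and B differed from C of its own diet by rho -0.23, while the 5 ppm libraries differed from each other by rho -0.05. A property of library B alone cannot be told apart from a part shared by the diet, because the value without it lies between what each would give. RNA integrity and fragment sizes were not analysed here.

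In the no-manganese library B, the mucin Muc11A had 28.3 RPKM, against at most 0.0842 RPKM in the other 3 libraries. In the deposited table the first 93 genes were lower without manganese and the next 81 higher, and 1621 genes came before the rest in order of identifier; what this order rests on is not given in the sources used here.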
